A study of Arabidopsis thaliana with 22 samples.

How the data were processed

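Per the labels, total RNA was taken from whole Arabidopsis thaliana seedlings with RNeasy columns and DNase digestion and made into TruSeq libraries. The seedlings had grown for 14 days on soil, under 16 h days at 22 °C and 8 h nights at 18 °C, about 150 µmol of light and 50% humidity. They were given ultraviolet light at 312 nm, a UV-B wavelength, at a fluence rate of 4.35 W per square metre, or a mock treatment, and were harvested 3 h later. The length of the exposure is not given in the sources used here. The 22 libraries came from 6 accessions (Ba-1, C24, Got-7, Lip-0, Mh-0 and T1080), which are inbred natural strains. They made up 12 groups of accession and treatment, with 2 libraries in 10 groups and 1 library in 2 groups (Got-7 UV and T1080 mock). The labels do not say that the libraries of a group came from separately grown plants. P-values therefore measure the spread between these samples, which may be technical. That spread may also hold genotype differences, since the values at several loci went against the labels.

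The deposited values were whole-number counts per locus, with no normalization, for 24185 loci. FastQC, TopHat and the builds TAIR9 and TAIR10 are named in the submitters' processing notes, with no versions and no roles. The counting program and its annotation are not given in the sources used here, nor is whether it used strand. All columns were matched to samples through the number in their names and in the sample descriptions, and 0 columns were left unmatched. Gene symbols came from a RefSeq gene table of assembly TAIR10.1, matched by locus code, which held 23847 of the 24185 loci. No coordinates were used. Of the loci, 1551 had 0 counts in every library.

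The total counts per library ran from 3539510 to 20903894, with a median of 9264888.5. They were 3539510, 6987725, 10919565 and 7441861 for Ba-1 (mock 1, mock 2, UV 1 and UV 2) and 6423024, 9844746, 20903894 and 7059048 for C24. Got-7 (mock 1, mock 2 and UV 1) had 6085171, 11622775 and 4893285, and Lip-0 had 7012967, 9583508, 10264646 and 13709473. Mh-0 had 9448579, 6402500, 19546141 and 10196352, and T1080 (mock 1, UV 1 and UV 2) had 7963857, 9451357 and 9081198. A count of 3, taken as the limit of what a count of 0 allows, equals 0.848 CPM (counts scaled to the total of their library) in the shallowest library and 0.144 CPM in the deepest. Intervals and limits of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

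Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors). One model of 12 group means was fitted to all 22 libraries, so that groups of 1 library were assumed to vary like the others. The 18149 loci with at least 1 CPM in at least 2 libraries were tested. The biological coefficient of variation was 26.7%. P-values were adjusted by Benjamini and Hochberg within each of 21 contrasts, and an adjusted p under 0.05 was called. The contrasts were the mean UV effect, the UV effect in each accession, the difference of UV effects between accessions (F test), the departure of each accession's UV effect from the mean of the other 5, the difference of mock levels (F test) and the departure of each accession's mock level. Errors are standard errors of the log2 fold change, taken from the fold change and its F statistic.

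Lists of genes were tested with camera from limma 3.58.1 on voom weights (preset correlation 0.01), and again with an estimated correlation and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, in 1 direction and makes no comparison with other genes. The lists were flavonoid biosynthesis, general phenylpropanoid and lignin, UVR8 photomorphogenic signalling, photolyase with excision repair and bypass, DNA damage checkpoint and recombination, camalexin and tryptophan biosynthesis, salicylic acid defence, jasmonate, ethylene, pattern-triggered immunity, NLR resistance loci, oxidative stress and detoxification, heat shock and unfolded protein, nuclear photosynthesis, mitotic cell cycle, DNA replication, auxin with brassinosteroid and elongation, senescence and cell death, circadian clock, known natural variation loci, root markers and flower markers. These 22 lists held 403 members, of which 368 were tested, 10 were not in the table and 2 (RPW8.1 and RPW8.2, planned with the NLR loci) were left out because the reference symbol contradicted the list. Lists with fewer than 5 tested members were given as values only. "Adjusted over the list alone" means adjusted within the members of 1 list.

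The design, the lists, the contrasts, the alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule named up to 8 rises and 8 falls that passed for the mean UV effect, of which there were 0, and list members with the smallest p for the mean UV effect (up to 4 of a list) or in a contrast where their list passed (up to 3). It also named the 2 largest rises and falls in each accession, the 12 genes with the smallest p for the difference in response, the 10 for the mock levels, the 2 in each departure and the natural variation loci. Minimum log2 CPM levels of 2 or 3 applied. The alternatives were RLE and upper quartile factors, no filter, a minimum of 5 CPM, DESeq2 1.42.0, limma voom, nuclear genes only, the replicate number as a block, only the groups compared, a log2 fold change of at least 1 or an adjusted p under 0.01, and leaving out each library or accession. Leaving out each library for the correlations of fold changes and for the salicylic acid and jasmonate lists was chosen after the data were seen.

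Libraries were compared with each other by Pearson correlation of TMM-scaled log2 CPM with a pseudocount of 1 over the 18149 tested loci, and after thinning all libraries to 3539510 counts. The agreement of nearest libraries with their labels was tested against 100000 permutations of the labels. The tests were run first on simulated counts for the 18149 genes, with 200 genes changed in the mean UV effect. The simulated spread was estimated from the real counts in the labelled groups, so it carries any mixing of genotypes within them. edgeR recovered 53.7% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 7 false calls among 149. On the same counts DESeq2 made 41 false calls among 193 and limma voom 5 among 143. Other steps used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.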

Results

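Whole seedlings of 6 Arabidopsis accessions were profiled by RNA sequencing 3 h after UV or mock treatment. The 22 libraries comprised 11 labelled mock and 11 labelled UV, at 3539510 to 20903894 counts each. Groups are written as labelled throughout, because the values at several loci went against the labels.

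Loci known to differ between accessions were examined first, since each should take 1 level within an accession. AOP3 (AT4G03050), a glucosinolate side chain gene, stood at 387 CPM in Got-7 mock 2 and 411 CPM in Got-7 UV 1. In Got-7 mock 1 it stood at 0.159 CPM, under the limit that a count of 0 allows in that library (0.493 CPM). It was also expressed in T1080 UV 1 and UV 2 (49.9 and 60.7 CPM) but stood at 0.229 CPM in T1080 mock 1. FLC (AT5G10140), a repressor of flowering, was at 83.8, 76.3 and 119 CPM in C24 mock 1, mock 2 and UV 1 and at 1.93 CPM in C24 UV 2. ESP (AT1G54040), which steers glucosinolate breakdown towards epithionitriles, was at 30.1 CPM in Ba-1 mock 1 and 2768 CPM in Ba-1 mock 2. GSL-OH (AT2G25450), which hydroxylates a glucosinolate side chain, was at 192 CPM in Mh-0 UV 2 and 18.4 CPM in Mh-0 UV 1. The resistance gene LAZ5 (AT5G44870) was at 0.179 CPM in Got-7 mock 2 and 21.5 CPM in Got-7 mock 1.

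**Figure D1:**
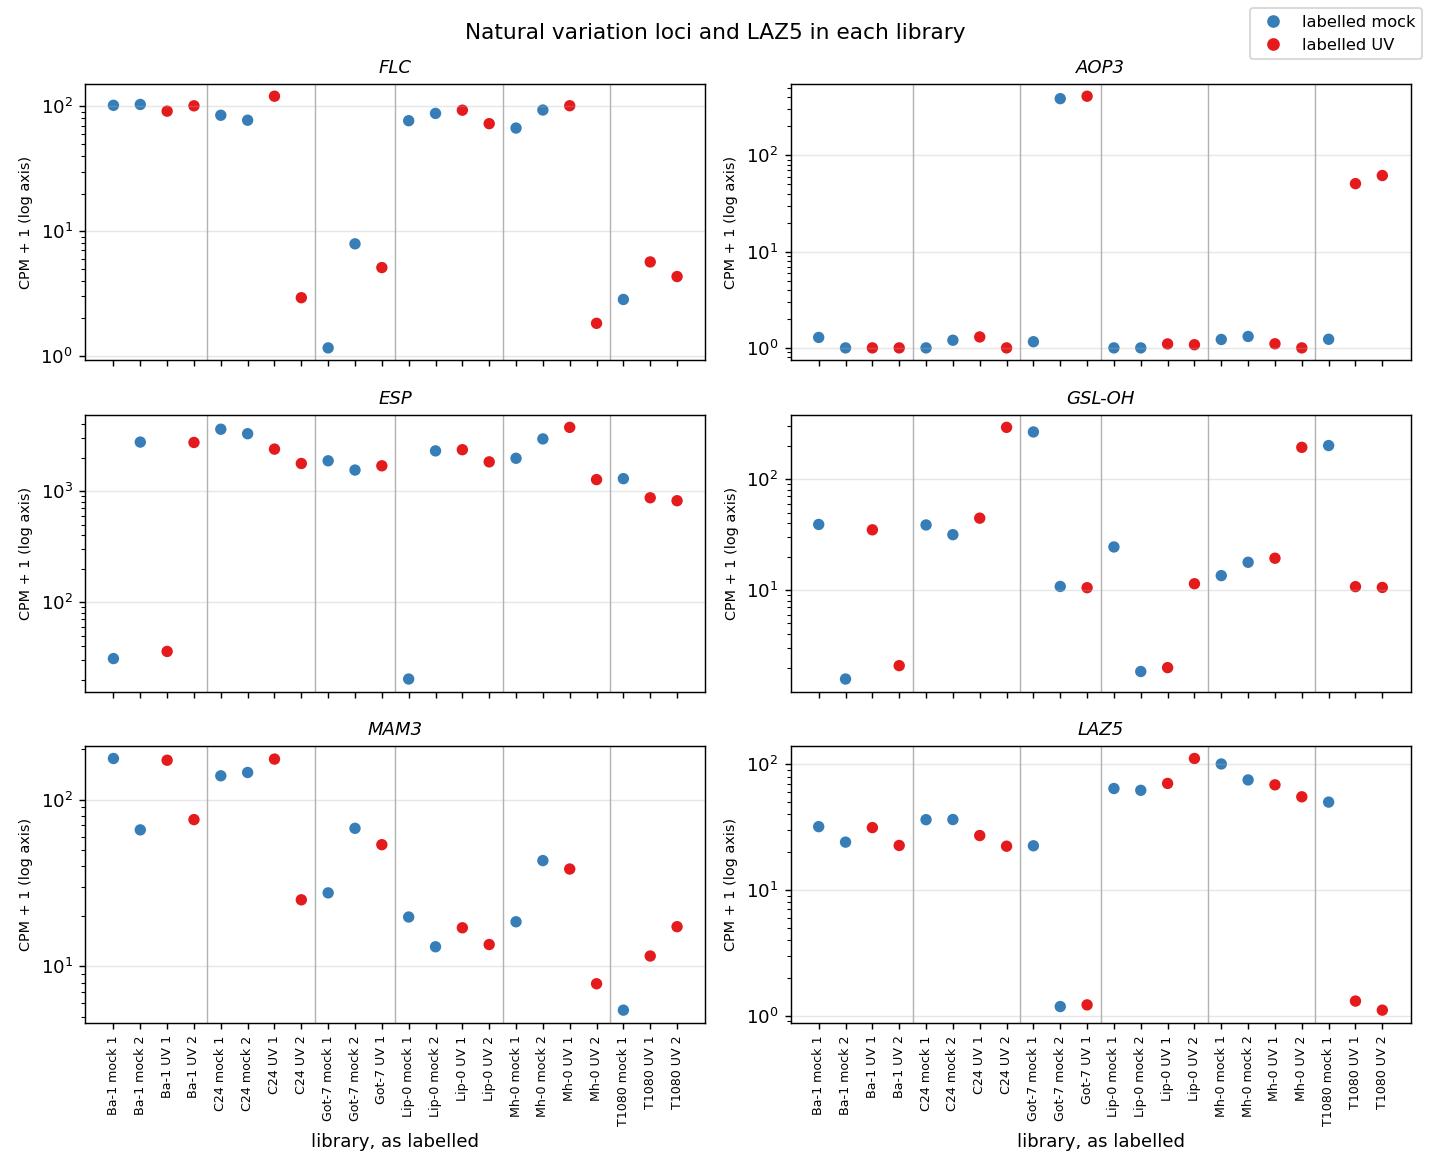
CPM + 1 on a log axis for 5 natural variation loci and LAZ5 in each of the 22 libraries, in label order, with 1 point per library coloured by labelled treatment. AOP3 reached 49.9 to 411 CPM in 4 libraries and stayed at or under 0.314 CPM in the other 18, and this border ran through labelled accessions.

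The labelled replicates were also compared over all 18149 tested loci. Of the 20 libraries with a labelled replicate, 4 had their nearest library, by Pearson correlation, within their own labelled group. The 22 libraries formed 10 pairs of mutually nearest libraries, with r between 0.975 and 0.995. Of the 10 labelled groups with 2 libraries, 2 were such pairs, C24 mock and T1080 UV. In 100000 permutations of the labels the mean was 0.434 pairs, and the one-sided permutation p for 2 or more was 0.07. Correlations between labelled replicates ran from 0.94 to 0.994. In a count made after the data were seen, 57 loci were under 0.5 CPM or at least 10 CPM in every library. A median of 14 of them differed in state within a labelled group of 2, against 0 within a mutually nearest pair. The spread that the tests used may therefore hold differences between genotypes, which could raise their p-values. Because some labels could not be reconciled with the values, no library was regrouped. Neither a direction nor an absence of a UV effect given here is firm.

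**Figure D2:**
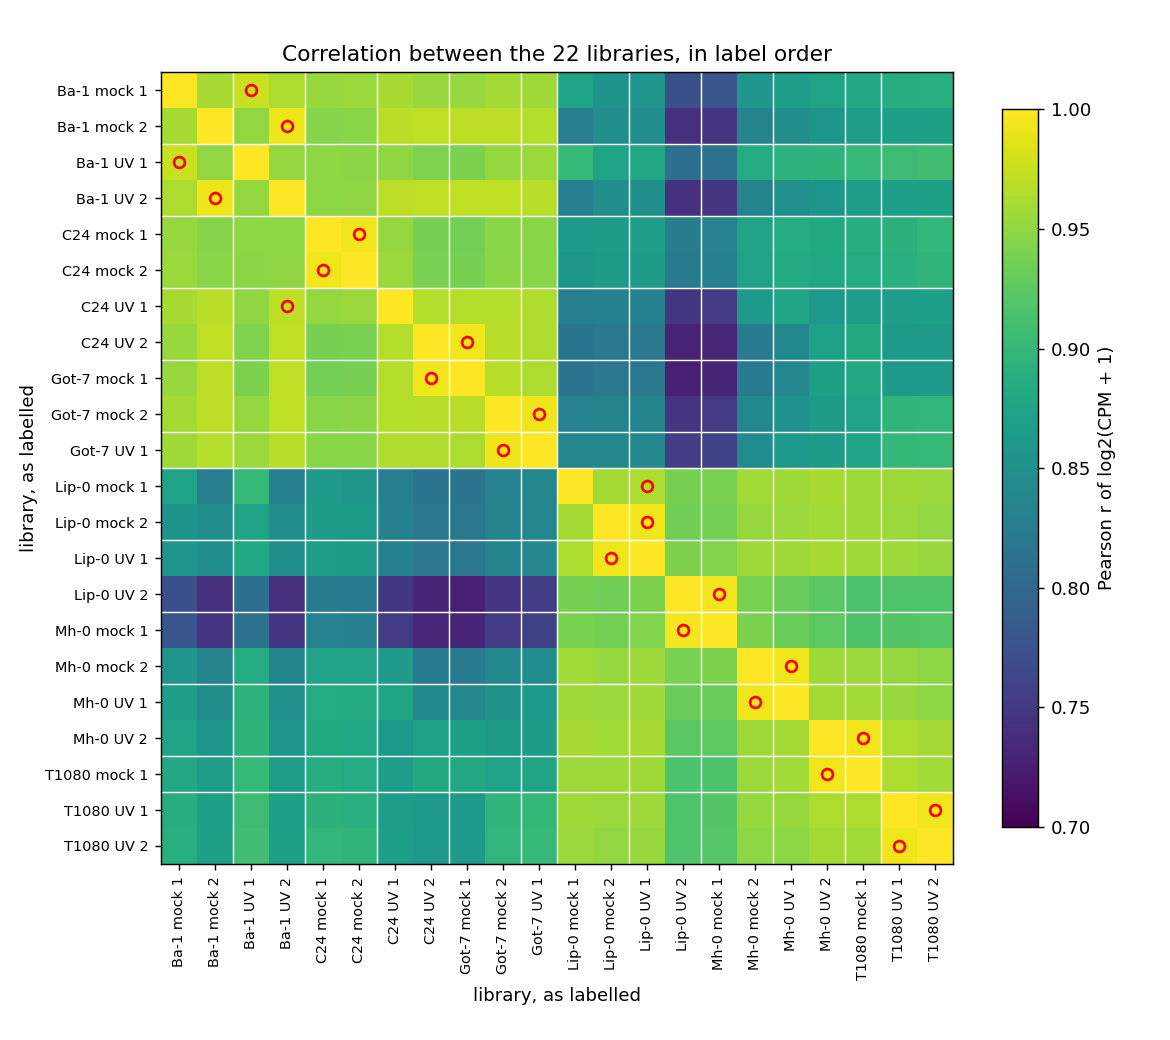
Pearson r of log2(CPM + 1) between all 22 libraries over 18149 loci, in label order, with white lines between labelled groups. A red circle in each line marks the library nearest to the one named at the left, and 4 of the 22 circles fall inside the labelled group, where 2 libraries had no labelled replicate.

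The first comparison asked which genes responded to UV on average over the 6 accessions. No gene passed with edgeR (0 genes, 504 at an unadjusted p under 0.05), and limma voom also gave 0. With labels in doubt, a count of 0 does not tell an absent response from groups that mixed libraries. In addition, 0 labelled accessions had libraries on both sides of the gap on the first principal component, which held 63.8% of the variance. UV contrasts within labelled accessions, and their mean, therefore could not show a difference between those sides. The resistance gene LAZ5 had the smallest p among the list members, at a mean log2 fold change of −2.32 ± 0.56 (SE, 11 libraries labelled UV and 11 mock, edgeR adjusted p = 1). It was near 0 CPM in 4 libraries that crossed the labelled accessions. The helper immune receptor ADR1 stood at −1.03 ± 0.32 and RPP1 at −1.22 ± 0.44, each with an adjusted p of 1. HSFB2A, a heat shock factor, stood at −0.57 ± 0.15, and the phytochrome-interacting factor PIL1 at −1.55 ± 0.64. The brassinosteroid gene DWF4 was at 0.29 ± 0.12 and the NAC factor NAC055 at 1.98 ± 0.95, again with adjusted p of 1.

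Of the 20 lists tested for the mean UV effect, camera called 2. The NLR resistance loci fell as a list (15 members, median log2 fold change −0.40, camera adjusted p = 0.00428), with an adjusted p = 0.69 with an estimated correlation. Adjusted over the list alone, 1 of the 15 was lower. Nuclear photosynthesis genes rose as a list (30 members, median 0.09, adjusted p = 0.00428), with an adjusted p = 0.955 with an estimated correlation. The other 18 lists had camera adjusted p between 0.165 and 0.91. Among them, the UVR8 signalling list had a median of −0.05 over 17 members and the flavonoid biosynthesis list −0.04 over 19. The photolyase, excision repair and bypass list was at −0.01 over 24 members, and the DNA damage checkpoint and recombination list at −0.01 over 22. Adjusted over the list alone, no member of these 4 lists was called. Median changes were −0.23 for salicylic acid, −0.11 for pattern-triggered immunity, 0.11 for jasmonate, 0.09 for oxidative stress and 0.30 for senescence genes. They were −0.08 for heat shock, −0.05 for auxin, brassinosteroid and elongation, −0.06 for clock, −0.02 for ethylene and −0.01 for general phenylpropanoid genes. The camalexin and DNA replication lists were at 0.00 and the mitotic and natural variation lists at 0.01. HSFB2A alone was lower in its list when adjusted over the list alone. DESeq2 called 2 genes, PNP-A and AT2G45220, named here after their values were seen because they were so few. Without Got-7 mock 2 the edgeR count was 7 and without Lip-0 UV 2 it was 1.

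The UV effect was next tested within each accession, and in C24 it reached 49 genes, 12 higher and 37 lower in the libraries labelled UV (2 against 2, edgeR). PNP-A (AT2G18660), a natriuretic peptide homologue linked to defence, fell by 7.42 ± 1.11 on the log2 scale (adjusted p = 0.0244). Its levels were 113 and 118 CPM in C24 mock and 0.648 and 0.688 CPM in C24 UV. RLP23 (AT2G32680), a receptor of the necrosis-inducing peptide nlp20, fell by 6.49 ± 1.18 (adjusted p = 0.0491). ARAB-1 (AT1G28670) rose by 2.80 ± 0.45 (adjusted p = 0.0317), from 4.18 and 4.93 CPM to 32.2 and 31.6 CPM. AT4G25260 rose by 1.94 ± 0.28 (adjusted p = 0.0214). The count depended on the tool and the fit, at 635 genes with DESeq2, 52 with limma voom and 1743 when only the groups compared were fitted. Both C24 UV libraries were nearest to libraries of other labels, UV 1 to Ba-1 UV 2 (r = 0.971) and UV 2 to Got-7 mock 1 (0.993). The C24 genes, and the C24 lists below, thus cannot be told from a difference between genotypes.

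Salicylic acid defence genes fell in C24 as a list (24 members, median −3.28, camera adjusted p = 6.63e-12), with an adjusted p = 0.686 with an estimated correlation. No member passed over all genes, and 19 were lower when adjusted over the list alone. DMR6 stood at −4.51 ± 0.87 (adjusted p = 0.0555), CBP60G at −3.72 ± 0.77 (0.0665) and WRKY62 at −3.40 ± 0.72 (0.0696). Pattern-triggered immunity genes (median −0.73, camera adjusted p = 0.00141) and NLR loci (median −0.79, 0.00495) also fell as lists, with adjusted p = 0.849 and 0.686 with an estimated correlation. Adjusted over the list alone, 5 and 1 of their members were lower, and the immunity gene WRKY18 stood at −3.02 ± 0.67 (adjusted p = 0.0766 over all genes). The C24 count rested on single libraries, at 1, 1, 3 and 0 genes without C24 mock 1, mock 2, UV 1 or UV 2. It was 118, 119, 141 and 138 without Ba-1 mock 1, mock 2, UV 1 or UV 2, 31 without Got-7 mock 1 or mock 2, and 91 or 94 without Lip-0 UV 1 or UV 2. Without Mh-0 mock 1 or mock 2 it was 268 or 271, without either Mh-0 UV library 20, and without either T1080 UV library 14.

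In T1080, with 1 library labelled mock, 1 gene passed with edgeR and with limma voom, against 47 with DESeq2 and 3351 when only the groups compared were fitted. NSP1 (AT3G16400), a nitrile-specifier protein of glucosinolate breakdown, fell by 1.65 ± 0.18 (adjusted p = 0.00867), from 101 CPM in T1080 mock 1 to 31.3 and 33.0 CPM in T1080 UV. Related copies of NSP1 lie beside it in the genome, so its level is uncertain if reads were split between them. The indolic glucosinolate gene CYP79B3 stood at −1.53 ± 0.29 (adjusted p = 0.248). The UVR8 signalling list fell (17 members, median −0.46, camera adjusted p = 1.02e-04), as did the flavonoid list (median −0.75, 2.59e-04), with adjusted p = 0.507 and 0.819 with an estimated correlation. In the UVR8 list the sigma factor gene SIG5 and the glutathione peroxidase gene GPX7 were at −1.22 ± 0.29 and −1.93 ± 0.50 (adjusted p = 0.41 and 0.45), and 2 members were lower when adjusted over the list alone. The count was 0 without T1080 UV 1 or UV 2 and 46 without Got-7 mock 1 or mock 2. It was 2 without any 1 of Ba-1 mock 1, Ba-1 mock 2, C24 mock 1, C24 mock 2, Mh-0 mock 1 or Mh-0 mock 2.

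No gene passed with edgeR in Ba-1, Got-7, Lip-0 or Mh-0, where 311, 305, 721 and 1750 genes had an unadjusted p under 0.05. Limma voom gave 0 in each, and DESeq2 gave 8, 1, 2 and 3. The DESeq2 genes, named after their values were seen, were AT3G47250 in Got-7, TGG2 and AT5G57890 in Lip-0, and AT4G29200, AT5G25920 and THI2.2 in Mh-0. In Ba-1 the camalexin gene CYP71B15 stood at 6.16 ± 1.84 and the glutathione transferase GSTU4 at 4.95 ± 1.43 (adjusted p = 1 for both). CYP71B15 was at 2.27 and 0.432 CPM in Ba-1 mock and at 162 and 0.540 CPM in Ba-1 UV. In Mh-0 the salicylic acid gene DLO1 stood at −4.59 ± 1.41 and NIMIN1 at −1.81 ± 0.57 (adjusted p = 0.512 for both). In Lip-0 DLO1 was at 3.52 ± 1.38 and the auxin-induced gene IAA1 at −1.18 ± 0.40 (adjusted p = 0.871 for both). In Got-7 WRKY62 stood at 6.38 ± 1.66 and the jasmonate-induced TAT3 at 8.46 ± 2.48 (adjusted p = 1 for both). Without Ba-1 UV 2 the Ba-1 count was 28, without Got-7 mock 2 the Got-7 count was 6, and without Mh-0 mock 2 the Mh-0 count was 486. The Lip-0 count was 15 without Lip-0 UV 1 and 2 without Lip-0 mock 2.

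The salicylic acid list was called upwards in 3 accessions and downwards in 2. It rose in Lip-0 (median 0.90, camera adjusted p = 1.4e-06), Got-7 (0.61, 0.0124) and T1080 (0.84, 0.0375), with adjusted p = 0.541, 0.877 and 0.819 with an estimated correlation. It fell in Mh-0 (median −1.41, adjusted p = 2.65e-08), with an adjusted p = 0.502 with an estimated correlation. Lip-0 UV 2 and Mh-0 mock 1, each other's nearest libraries (r = 0.995), were the highest library for 5 and 13 of its 24 members. Without Lip-0 UV 2 the Lip-0 median was 0.28 (camera adjusted p = 0.0269), and without Mh-0 mock 1 the Mh-0 median was −0.30 (0.00602). The Got-7 median was 0.83 without Got-7 mock 2 (0.171) and that of T1080 0.60 without T1080 UV 2 (0.164), so both calls ended. Without Got-7 mock 1 the Got-7 median was 0.40 (0.0364). In Ba-1 the list was not called (median 0.01, 0.33), but it was called upwards without Ba-1 mock 1 (1.04, 0.00317) or UV 2 (0.38, 0.0104) and downwards without Ba-1 mock 2 (−0.52, 0.00129).

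Jasmonate genes rose as a list in Ba-1 (median 1.13, adjusted p = 5.1e-06) and Got-7 (1.06, 4.28e-07), with adjusted p = 0.71 and 0.877 with an estimated correlation. They fell in Mh-0 (−0.49, 0.0444) and T1080 (−0.54, 0.03), with adjusted p = 0.651 and 0.819 with an estimated correlation. In Ba-1 the call ended without Ba-1 UV 1 (median −0.15, 0.747) or Ba-1 mock 2 (0.63, 0.343), and the median was 1.82 without Ba-1 UV 2. The Got-7 median was 0.62 without Got-7 mock 1 (0.00208) and 1.75 without Got-7 mock 2 (4.18e-05). The call ended in Mh-0 without Mh-0 mock 2 (−0.53, 0.259) or Mh-0 UV 2 (−0.10, 0.887), with a median of −0.89 without Mh-0 UV 1, and in T1080 without T1080 UV 2 (−0.50, 0.0865). In Lip-0 the list was not called (0.30, 0.0608), but it was called upwards without Lip-0 mock 1 (0.98, 0.00116) or UV 1 (0.77, 0.00128), and without Ba-1 UV 1 (0.0233), Ba-1 UV 2 (0.0365), Got-7 mock 1 (0.0457) or Got-7 mock 2 (0.0404). Camera called 6 lists in Ba-1, 3 in C24, 3 in Got-7, 8 in Lip-0, 12 in Mh-0 and 7 in T1080, and no member of any list passed over all genes in these 6 contrasts. None of these 39 list calls held with an estimated correlation or with fry. The DNA damage, DNA replication, circadian clock, natural variation and photolyase lists were called in 0 of the 6 accessions.

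UV effects were then compared between accessions. In the F test of all differences 0 genes passed with edgeR and with limma voom (1619 at an unadjusted p under 0.05), and DESeq2 called 345. The peptide transporter gene PTR3 had the smallest adjusted p (0.0769), followed by NSP1 (0.22), and PDIL1-3, AT5G43660 and MEE32 (0.474 each). AT4G15690, CRK15, PRORP3, CYP71B23, MSS1 and NAC001 were at 0.494 and PNP-A at 0.533. The count was 4 without Got-7 mock 1, 10 without Got-7 mock 2 and 1 without Lip-0 UV 1.

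Measured as the departure of 1 accession from the mean of the other 5, C24 had 12 genes, 4 with a higher and 8 with a lower response. PTR3 (AT5G46050) departed by −3.95 ± 0.39 (adjusted p = 0.00296), with 9.44 and 8.14 CPM in C24 mock and 0.848 and 0.550 CPM in C24 UV. MEE32 (AT3G06350), a shikimate pathway enzyme gene, departed by 0.97 ± 0.13 (adjusted p = 0.0349). In T1080 NSP1 departed by −1.65 ± 0.19 (adjusted p = 0.0189) and the neighbouring PBP1 by −1.85 ± 0.31 (adjusted p = 0.362). No gene departed in Ba-1, Got-7, Lip-0 or Mh-0 with edgeR or voom, where 360, 266, 1336 and 1946 genes had an unadjusted p under 0.05 and DESeq2 gave 2, 0, 5 and 0. The DESeq2 genes, named after their values were seen, were NATA1 and AT4G29200 in Ba-1 and AT1G66100, AT4G29200, TGG2, AT5G44570 and AT5G57890 in Lip-0. The smallest p in these accessions belonged to MEE67 and AT5G65600 in Ba-1, IMPA-9 and NSP1 in Got-7, AT5G57890 and HSFB2A in Lip-0, and AT3G59290 and AT2G38570 in Mh-0.

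Gene lists departed in each accession under camera, with 7 lists in Ba-1, 4 in C24, 4 in Got-7, 8 in Lip-0, 11 in Mh-0 and 7 in T1080. The salicylic acid list fell further in C24 (median −3.34, camera adjusted p = 2.07e-12) and Mh-0 (−1.76, 2.07e-05) than in the mean of the others, with adjusted p = 0.761 and 0.487 with an estimated correlation. It rose further in Lip-0 (1.43, 5.4e-06), with an adjusted p = 0.561 with an estimated correlation. In C24, 21 of its 24 members departed downwards when adjusted over the list alone. None of the 41 list calls held with an estimated correlation or with fry. The 12 C24 genes became 2, 1, 1, 2 and 0 without Ba-1 mock 2, C24 mock 1, C24 mock 2, C24 UV 1 and C24 UV 2. They became 5 without Ba-1 UV 1, 2 without Lip-0 mock 2, and 1 without Lip-0 mock 1, Mh-0 UV 1, Mh-0 UV 2, T1080 mock 1, T1080 UV 1 or T1080 UV 2. The count rose to 44 without Ba-1 mock 1, 88 without Ba-1 UV 2, 41 without Got-7 mock 2, 30 without Lip-0 UV 1, 267 without Mh-0 mock 1 and 27 without Mh-0 mock 2. The T1080 departure was 0 genes without C24 mock 2, T1080 UV 1 or T1080 UV 2, 28 without Got-7 mock 1 and 4 without Got-7 mock 2. For the accessions at 0, the count was 13 for Ba-1 without Ba-1 UV 2 and 2 without Got-7 mock 2. It was 21, 3 and 2 for Lip-0 without Lip-0 UV 1, Lip-0 mock 2 or Got-7 mock 2, and 220 and 1 for Mh-0 without Mh-0 mock 2 or Got-7 mock 2.

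A response shared by accessions was sought in the correlation of fold changes, which share no library between accessions. The overlap of calls held no information, with 0 genes called in 4 of the 6 accessions and 1 in T1080. Over the 15 pairs of accessions the median Pearson r across 18149 genes was −0.111, with a range of −0.513 (Lip-0 and Mh-0) to 0.585 (C24 and Mh-0), and 6 pairs were above 0. Single libraries moved these values, and r of Lip-0 and Mh-0 was −0.0287 without Lip-0 UV 2 and −0.0927 without Mh-0 mock 1. For C24 and Mh-0 it was 0.107 without Mh-0 mock 1. The median r was 0.026 without Ba-1 UV 1, −0.0407 without Ba-1 mock 2, −0.0397 without C24 UV 2 and −0.0167 without Got-7 mock 1. It was −0.0287 without Lip-0 UV 2, −0.0657 without Mh-0 mock 1 and −0.0165 without Mh-0 UV 2. The median Spearman rho was −0.109. Over the 12965 genes with a mean log2 CPM of at least 3 the median r was −0.159. These are correlations across genes, which are not independent replicates.

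The last comparison asked how mock levels differed between accessions, and it called 7502 genes (5 degrees of freedom, 11 libraries labelled mock, edgeR). Libraries labelled Ba-1, C24 or Got-7 lay apart from those labelled Lip-0, Mh-0 or T1080 on the first principal component, which held 63.8% of the variance. Mock differences here and below are not separated from that border, and the labels did not mark single genotypes. They are therefore not given as natural variation between accessions. The smallest p belonged to HSP23.5 (AT5G51440), a small heat shock protein of mitochondria (adjusted p = 2.14e-09). It stood at 0.796 to 3.41 CPM in the 11 libraries labelled Ba-1, C24 or Got-7 and at 222 to 290 CPM in the 11 labelled Lip-0, Mh-0 or T1080, whichever treatment was labelled. The mitochondrial chaperone gene mtHsc70-1 (adjusted p = 5.1e-08) ran from 160 to 222 CPM in the first 11 and from 674 to 915 CPM in the others. The glutathione transferase GSTU9 (1.78e-07) ran from 0 to 1.70 CPM and from 228 to 429 CPM, and the light stress gene ELIP2 (1.78e-07) from 0 to 0.851 CPM and from 69.7 to 154 CPM. AT3G58150, AT5G54100, MTM1, AT4G38860, PP2C5 and AT5G66070 completed the 10 smallest, with adjusted p from 3.73e-08 to 2.13e-07. Among the natural variation loci, AOP3 (adjusted p = 0.00302), MAM1 (0.0313) and MAM3 (0.0315) passed. For AOP3 this rested on 1 of the 11 libraries labelled mock, Got-7 mock 2 (387 CPM), with its labelled replicate at 0.159 CPM. FLC (0.167), GSL-OH (0.341), FRI (0.55) and ESP (0.958) did not pass. Mock replicates of Ba-1 stood far apart for ESP (30.1 and 2768 CPM) and GSL-OH (38.0 and 0.576 CPM), while FRI ran only from 5.39 to 12.4 CPM over all libraries.

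**Figure D3:**
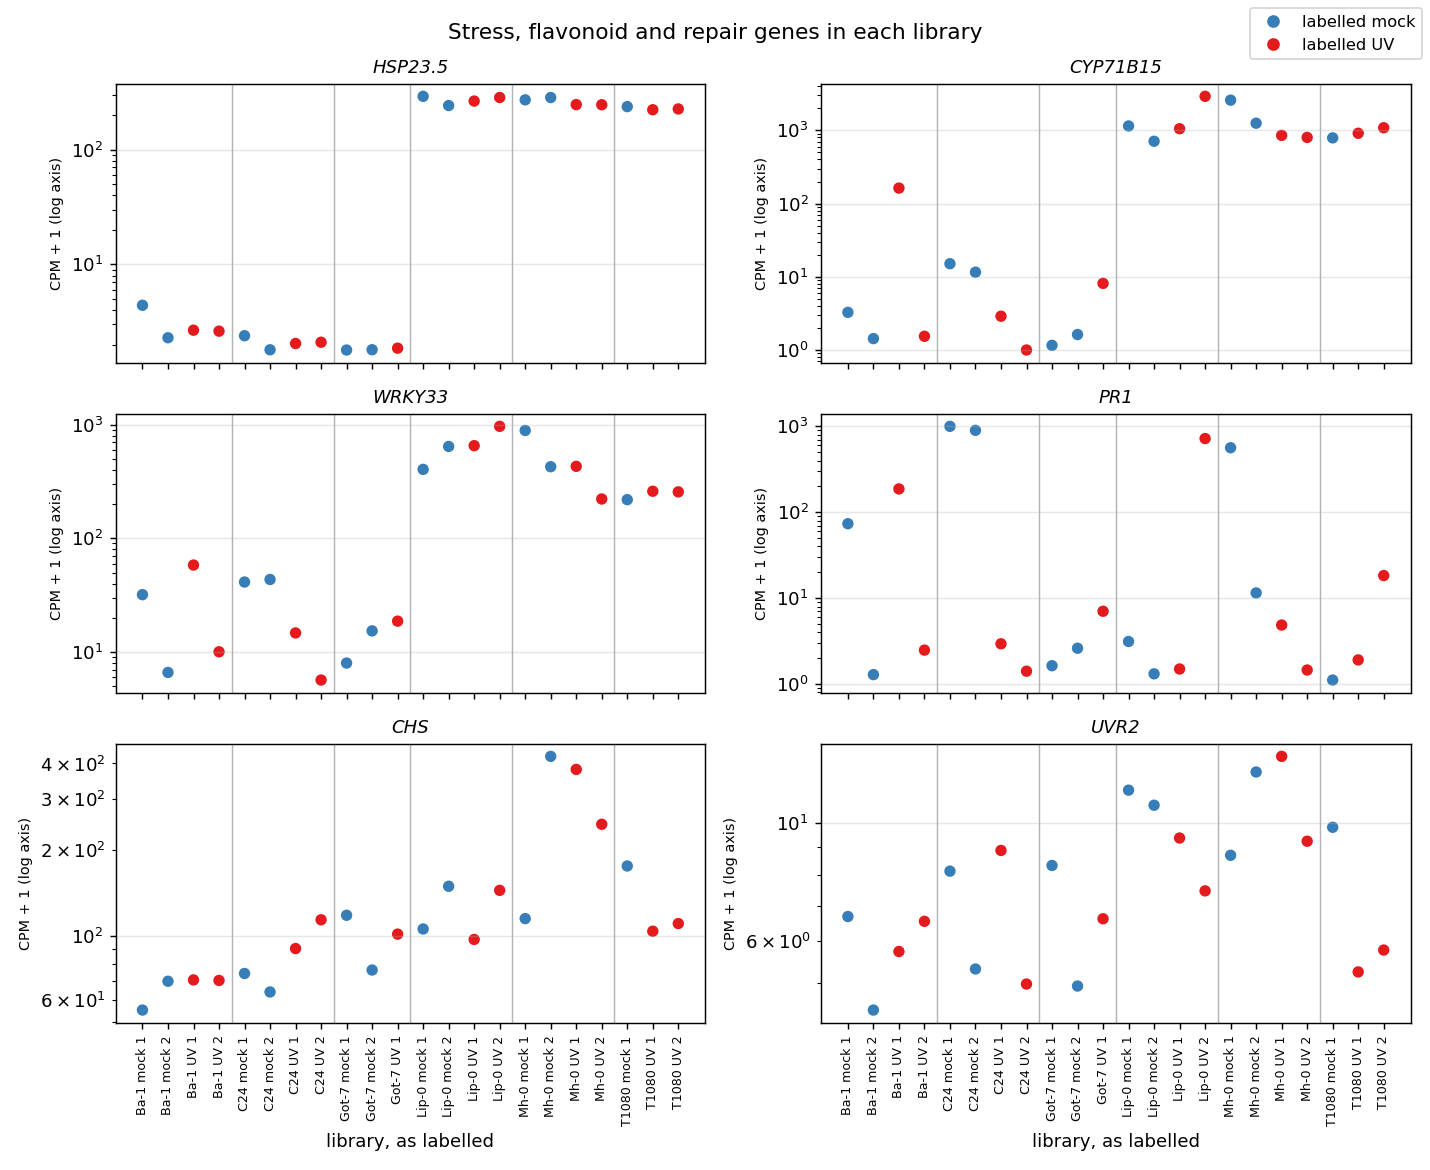
CPM + 1 on a log axis for the mitochondrial chaperone HSP23.5, the defence genes CYP71B15, WRKY33 and PR1, the flavonoid gene CHS and the photolyase gene UVR2 in each library, in label order and coloured by labelled treatment. HSP23.5 stands at 222 to 290 CPM in all 11 libraries labelled Lip-0, Mh-0 or T1080 and at most 3.41 CPM in the other 11.

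Against the mean of the other 5 accessions, 3296 genes departed in Ba-1 mock (1734 higher, 1562 lower), 2833 in C24 (1503, 1330) and 4590 in Got-7 (2227, 2363). The numbers were 3628 in Lip-0 (2332, 1296), 6736 in Mh-0 (4004, 2732) and 636 in T1080 (513, 123), where 1 library was labelled mock. HSP23.5 was lower in Ba-1 (−3.67 ± 0.26), C24 (−4.87 ± 0.27) and Got-7 (−5.34 ± 0.28) and higher in Lip-0 (4.67 ± 0.16), Mh-0 (4.75 ± 0.16) and T1080 (4.46 ± 0.17), with the largest edgeR adjusted p at 2.28e-05. AOX1A, the alternative oxidase of mitochondria, was lower by a log2 difference of −2.86 ± 0.32 in Ba-1 and higher by 3.13 ± 0.22 in Mh-0 (adjusted p = 2.25e-04 and 2.16e-06). The immune kinase gene BIK1 was at −1.90 ± 0.20 in Ba-1 and 2.27 ± 0.14 in Lip-0 (1.55e-04 and 6.68e-07). PARP2, a DNA damage response gene, was at −1.14 ± 0.13 in Ba-1 and 1.06 ± 0.11 in Mh-0 (2.36e-04 and 2.25e-05).

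Pattern-triggered immunity genes were lower as a list in mock libraries of Ba-1 (median −1.90, 16 of 25 called lower), C24 (−0.74, 7 of 25) and Got-7 (−2.08, 20 of 25). They were higher in Lip-0 (median 2.19, 20 of 25 called higher), Mh-0 (2.05, 23 of 25) and T1080 (1.27, 7 of 25). Their largest camera adjusted p was 3.12e-04, and with an estimated correlation their adjusted p ran from 0.147 in Lip-0 to 0.42 in C24. Heat shock genes followed with medians of −1.57, −1.66 and −2.54 in Ba-1, C24 and Got-7 and 2.29, 2.56 and 1.43 in Lip-0, Mh-0 and T1080. With an estimated correlation their adjusted p was lowest in T1080 (adjusted p = 0.0842) and highest in C24 (adjusted p = 0.42). DNA damage checkpoint and recombination genes were lower in Ba-1 (median −0.56), C24 (−0.53) and Got-7 (−0.37) and higher in Lip-0 (0.41), Mh-0 (0.43) and T1080 (0.61). In Lip-0 11 of the 22 were called higher, and the list held there with an estimated correlation (adjusted p = 0.04), the only 1 of 380 list tests to do so. Mitotic cell cycle genes went the other way, from a median of 0.61 in Ba-1 to −0.75 in Mh-0, with adjusted p = 0.26 and 0.28 with an estimated correlation. Nuclear photosynthesis genes stood at 0.45 in Ba-1 and −0.47 in Mh-0, with adjusted p = 0.451 and 0.417 with an estimated correlation.

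The camalexin, oxidative stress and detoxification, jasmonate, ethylene, and general phenylpropanoid and lignin lists were each called lower in 3 accessions and higher in 3. Each departure is taken from the mean of the other 5 accessions, so the 6 share libraries and are not separate findings. Oxidative stress genes, for example, had a median of −2.85 in Ba-1 and 3.00 in Mh-0, with adjusted p = 0.225 and 0.227 with an estimated correlation. Camera called 14 lists in Ba-1, 11 in C24, 15 in Got-7, 12 in Lip-0, 14 in Mh-0 and 13 in T1080. Fry called 68 lists in these contrasts, 57 of them among the 79 of camera. The circadian clock, natural variation and photolyase lists were called in 0 of the 6 mock contrasts. With upper quartile factors the share of higher calls was 60.6% in Got-7 and 42.7% in Mh-0, against 48.5% and 59.4%, and the median of all genes shifted by 0.11 and −0.17. No called list's median changed sign under either other scaling. The Ba-1 count was 1411 and 642 without Ba-1 mock 1 and mock 2, C24 508 and 359, Got-7 2050 and 1589, and Lip-0 1922 and 1838, each without its own mock 1 and mock 2. It was 2218 for Mh-0 without Mh-0 mock 1, and 411 and 415 for T1080 without C24 mock 1 and mock 2.

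Transcripts of the organelle genomes took 0.0441% (Ba-1 UV 1, 95% Wilson interval 0.0429 to 0.0454) to 0.51% (Mh-0 UV 2, 0.506 to 0.515) of the counts. The mean share was 0.178% ± 0.137 (SD, n = 11) in libraries labelled UV and 0.192% ± 0.128 (SD, n = 11) in those labelled mock. The mean within-accession difference was −0.0346 percentage points (exact permutation test over 11664 assignments, two-sided p = 0.461). The share was 0.134% to 0.51% in libraries labelled Lip-0, Mh-0 or T1080. It was at most 0.12% in those labelled Ba-1, C24 or Got-7, except Ba-1 mock 1 (0.403%). A permutation within labelled accessions cannot show a difference of this kind. Of the root markers, PYK10 was at 51.5 to 269 CPM and NRT2.1 at no more than 1.38 CPM. Of the flower markers, AG reached 1.42 CPM, SEP3 4.32 CPM and FUL 3.18 CPM, so both lists had too few tested members for a test.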

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

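The tests of departures in this part were chosen before their results were seen. The count of split loci, and which of them to name, were chosen after. Each result below is a UV effect that differed between accessions by a test of the difference itself, as labelled. In C24 12 genes departed from the mean of the other 5 accessions, among them PTR3 (log2 difference −3.95) and MEE32 (0.97). In T1080 1 gene departed, NSP1 (−1.65). In C24 both libraries of each arm lay on the same side for PTR3, at 9.44 and 8.14 CPM against 0.848 and 0.550 CPM. C24 UV 1 was nearest to Ba-1 UV 2 (r = 0.971) and C24 UV 2 to Got-7 mock 1 (0.993). Their r to the C24 mock libraries was 0.938 to 0.954. AT1G63880, AT1G66100 and AT3G44430 were expressed in both C24 mock libraries and in neither C24 UV library. The departure in C24 thus cannot be told from a difference between genotypes. The departure in T1080 rests on 1 library labelled mock, which was nearest to Mh-0 UV 2 (r = 0.993, against 0.963 and 0.958 to the T1080 UV libraries) and differed from them in AOP3 (0.229 against 49.9 and 60.7 CPM), so it cannot be told from a difference between genotypes.

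Lists of genes departed from the mean of the other accessions in every accession under camera with its preset correlation. There were 7 lists in Ba-1, 4 in C24, 4 in Got-7, 8 in Lip-0, 11 in Mh-0 and 7 in T1080, and none passed with an estimated correlation. The salicylic acid list departed in all 6, upwards in 4 and downwards in 2. Libraries of 1 labelled group stood at opposite levels of FLC in C24 and Mh-0 UV, of ESP in Ba-1 mock, Ba-1 UV and Lip-0 mock, of AOP3 in Got-7 mock and of GSL-OH in both Ba-1 and both Lip-0 groups. For FLC in C24 UV the levels were 119 and 1.93 CPM, and C24 was split at 33 of 57 loci that were under 0.5 CPM or at least 10 CPM in every library. The lower bound lies under the limit of the shallowest library (0.848 CPM) and the upper bound above it. For this reason no departure is given as a property of an accession.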

How the results depend on the processing

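The fit to the 4 accessions with 2 libraries in each arm and the correlations without each library were chosen only after the data were seen, and all other alternatives here were planned. RLE factors, no filter, limma voom and nuclear genes only kept all 21 counts within 1.5 times of the reported ones. DESeq2 called 2 genes for the mean UV effect, 8 in Ba-1, 635 in C24, 1 in Got-7, 2 in Lip-0, 3 in Mh-0 and 47 in T1080. It called 345 for the difference of UV effects and 2, 519, 5 and 32 for the departures of Ba-1, C24, Lip-0 and T1080. On simulated counts it made 41 false calls among 193, and the cause of the difference was not tested. Upper quartile factors gave 74 in C24 and 2 in T1080, and a minimum of 5 CPM gave 2 in T1080. Fitting only the groups compared gave 1743 in C24 and 3351 in T1080. The 4 accessions with 2 libraries in each arm gave 1 gene for the mean UV effect, PTR3. A log2 fold change of at least 1 left 1364, 1103, 1811, 1753 and 2998 mock departures in Ba-1, C24, Got-7, Lip-0 and Mh-0, and an adjusted p under 0.01 left 4673 genes in the F test of mock levels, as stricter thresholds must. Of 161 list calls in 380 tests, 1 held with an estimated correlation, and fry gave 68. For the mean UV effect camera called 4 lists without Ba-1, 4 without Lip-0 and 5 without Mh-0. For the other changes the cause was not tested.

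Same-numbered libraries deviated together in Ba-1 (r = 0.626) but not in C24 (−0.000773), Lip-0 (−0.341) or Mh-0 (−0.277), so the numbers were not taken to pair the samples. With the replicate number as an additive block the counts were 20 in C24, 1 for its departure and 0 for the departure of T1080. With numbered pairs as the block they were 343 in C24, 1 for the difference of UV effects, 185 for the departure of C24, 1 for that of Got-7 and 0 for that of T1080. The block moved no other count.

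Leaving out each library in turn gave 0 to 7 genes for the mean UV effect, 0 to 28 in Ba-1, 0 to 271 in C24, 0 to 6 in Got-7, 0 to 15 in Lip-0, 0 to 486 in Mh-0 and 0 to 46 in T1080. It gave 0 to 10 for the difference of UV effects and 0 to 13, 0 to 267, 0 to 21, 0 to 220 and 0 to 28 for the departures of Ba-1, C24, Lip-0, Mh-0 and T1080. For mock levels it gave 642 to 4304 in Ba-1, 359 to 3473 in C24, 1589 to 5751 in Got-7, 1838 to 4728 in Lip-0, 2218 to 7631 in Mh-0 and 411 to 866 in T1080. The median correlation of UV fold changes (−0.111) was 0.026 without Ba-1 UV 1, −0.0407 without Ba-1 mock 2, −0.0397 without C24 UV 2, −0.0167 without Got-7 mock 1, −0.156 without Got-7 mock 2, −0.0287 without Lip-0 UV 2, −0.0657 without Mh-0 mock 1 and −0.0165 without Mh-0 UV 2. A lone library was assumed to vary like the other groups. Leaving out the lone library of Got-7 UV or of T1080 mock gave no value for the contrasts that need it. Of 17999 values of named genes under alternatives, 17523 kept their side of the threshold, 318 lost it, 158 gained it and 0 reversed. At 3539510 counts, the shallowest library does not resolve levels under 0.848 CPM.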

Other observations

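Of the tests in this part, those of column numbers, of single wrong labels, of the labelled treatment and of the labelled genotype, and the spread of gene lists over libraries, were chosen only after the result was seen. Without regard to labels, the gene groups differed widely in how much they varied over the 22 libraries. Of the 20 lists, 10 lay at percentile 100 of 10000 random lists matched in size and mean expression, led by the natural variation loci with a median SD of 2.23 in log2 CPM. The camalexin and tryptophan list had a median SD of 1.73 over its 12 members, the oxidative stress list 1.58 over 27, the salicylic acid list 1.56 over 24, the senescence list 1.54 over 10 and the pattern-triggered immunity list 1.51 over 25. The others were the heat shock list, just under the last of these, the NLR loci (1.39), jasmonate (1.38) and ethylene (1.11), against a median SD of 0.375 for all loci. CYP71B15, the last enzyme of camalexin synthesis, ranged from 0 to 2913 CPM, the defence gene FMO1 from 0 to 1043 CPM and the glucosyltransferase gene UGT74E2 from 0 to 1434 CPM. In libraries labelled Ba-1, C24 or Got-7, FMO1 and UGT74E2 stood at no more than 9.39 and 9.2 CPM. In those labelled Lip-0, Mh-0 or T1080 they stood at 62.1 and 499 CPM or more. For CYP71B15 the widest gap did not follow this border, since Ba-1 UV 1 lay on its high side. Genes in this part outside the rule for named genes were chosen after their values were seen.

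The photolyase, excision repair and bypass list had a low median SD of 0.258 over 24 members, at percentile 1.49. Members of the repair list nevertheless varied, with SDs of 1.53 for CEN2, 0.763 for REV1, 0.679 for POLH and 0.461 for the photolyase gene UVR2 (3.46 to 12.3 CPM). The UV-B receptor gene UVR8 stayed between 87.3 and 142 CPM. The flavonoid list had a median SD of 0.58 (percentile 98.6), and CHS ranged from 54.2 to 423 CPM. The DNA damage list was at 0.448 (percentile 83.6), with BRCA1 at 12.2 to 23.9 CPM in the libraries labelled Ba-1, C24 or Got-7 and at 38.9 to 64.7 CPM in those labelled Lip-0, Mh-0 or T1080. NAC085 had 0 to 0.568 CPM in the first and 7.58 to 19.3 CPM in the second.

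The first pattern is that libraries labelled as replicates of 1 group were not nearest to each other. A single wrong label, or 1 swap of 2 libraries, would leave at least 8 of the 10 labelled groups of 2 intact, and 2 were. Unequal library depth is argued against, since after thinning all libraries to 3539510 counts there were again 2. The libraries still formed 10 mutually nearest pairs, which is consistent with the numbers of the count columns not following the numbers in the sample descriptions. That remains a hypothesis, found and tested on the same data, and no biological explanation was tested.

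The second pattern is that the 22 libraries lay in separate sets of 11 and 11 on the first principal component, which held 63.8% of the variance. The sets were exactly the libraries labelled Ba-1, C24 or Got-7 and those labelled Lip-0, Mh-0 or T1080, which are also the first 11 and the last 11 columns of the deposited counts. Unequal library depth is argued against, since the gap between the sets was 41.7% of the range after thinning, and so is the UV treatment as labelled, since 6 of the 11 libraries labelled UV lay above the gap and 5 below. That 0 labelled accessions had libraries on both sides does not favour the accession as labelled, since the labels run in column order, and 86% of 57 loci (under 0.5 or at least 10 CPM in every library) were split within a labelled accession while the other 8 followed the border. The labels thus did not mark single genotypes. AOP3 was expressed in Got-7 mock 2 and UV 1 and in T1080 UV 1 and UV 2. GSL-OH was low in Ba-1 mock 2 and UV 2 and in Lip-0 mock 2 and UV 1. ESP was low in Ba-1 mock 1 and UV 1 and in Lip-0 mock 1. FLC was low in C24 UV 2, Mh-0 UV 2 and all Got-7 and T1080 libraries. MAM1 and MAM3 were highest in the first set only, by smaller margins. For AOP3, GSL-OH, ESP and FLC the same states occurred in both sets, which argues against a genotype difference between them at these loci. A batch or a treatment under other labels may account for the sets. Neither was tested, and the values do not tell them apart. No UV contrast compared the sets, since each labelled accession lay within 1 of them.

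The third pattern is the count of 0 genes for the mean UV effect. Treatment was relabelled within accession, for 40 labellings including the real one, but this decides nothing, since a count of 0 is met by all 40 by construction. The highest other count was 20, against 0 for the labels, and 38 of the 40 gave 0. Simulated data of the same size, with 200 genes changed alike in all accessions, gave 149 calls. They held no differences between accessions and no labels in doubt, so they do not tell what limits the real count.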
